A study of Homo sapiens with 12 samples.

How the data were processed

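Total RNA from 2 human ovarian cancer cell lines was profiled on Illumina bead arrays with 47231 probes. A2780-PAR is labelled cisplatin-sensitive and A2780-CP20 cisplatin-resistant. Each line received a control siRNA or an siRNA against ATP11B, with 3 arrays in each of the 4 groups and 12 arrays in all. The deposited table that was not normalised holds 1 linear intensity per probe and array; detection p-values and control probes were not used here. Its lowest values per array lie between 27.6 and 34.5, and none is at or below 0. The authors also deposited log2 values, whose columns all share 1 distribution; they equal log2 intensities after quantile normalisation over the 12 arrays to within 0.005. BeadStudio is the only tool the labels name, and its version is not given.

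The linear intensities were background corrected by limma's normexp model (saddle estimate, offset 50), the fallback fixed beforehand,, log2 transformed and quantile normalised. Of the probes, 30113 carried the name of 1 gene, 17110 carried no gene name and 8 carried several. Each of 20046 genes was represented by its probe with the highest mean, so that 6691 genes with several probes entered the tests once. A mean per group was fitted to the 12 arrays together with limma, with empirical Bayes moderation. The contrasts were ATP11B siRNA minus control siRNA in A2780-PAR, the same in A2780-CP20, A2780-CP20 minus A2780-PAR under control siRNA, and the difference between both responses. P-values were adjusted over the genes of a contrast by the Benjamini-Hochberg method, and an adjusted p below 0.05 was called. ATP11B was also tested over its 2 probes alone and by two-sided exact permutation of group labels; 3 arrays against 3 cannot give an exact p below 0.1. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.

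The groups, these 4 contrasts, the gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The rule names ATP11B and the genes past the threshold whose 3 values in 1 group all lie on 1 side of the other group's; where none passes, as in all 4 contrasts, it names the 5 genes with the smallest p in each direction, said not to pass. There were 29 gene lists, on flippases, metal and drug transport, DNA repair, stress responses, vesicle traffic, metabolism, cell cycle, cell identity and other cell types. They were tested with limma's camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. Members were also adjusted over their list alone. That adjustment does not cover the 29 lists or the contrasts, so some lists hold a passing member by chance alone.

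Some choices were made after the data had been seen. The arrays labelled A2780-PAR ATP11B siRNA replicates 1 and 2 had very low signal, defined as a 95th percentile of intensity below 50% of the median of all arrays. All results were therefore recomputed from the other 10 arrays, normalised anew, which leaves 1 array in that group; its spread is assumed to equal that of the other groups. In this fit 2 contrasts were added, the mean response over both lines and the mean difference between the lines over both treatments, which brings its contrasts to 6. They were added after the 4 contrasts first chosen had given no calls. Alternatives covered the background step, the normalisation, the deposited log2 values, the arrays in the fit, array weights, the variance model, a replicate block, the threshold, the choice of probe and leaving out each array. For the 10 arrays they also covered a brightness filter and the removal of 1 or 2 axes of residual variation. The filter kept 9370 of 20046 genes, those with a probe above an intensity of 100 on all arrays of at least 1 group. In data simulated with the spread of the 10 arrays, the procedure recovered 94% of genes with a 2-fold change and 40% of those with a 1.5-fold change in the A2780-CP20 contrast. The simulated noise was independent between arrays, which measured arrays need not satisfy. The simulation changed 100 genes of each fold at once, all above the median brightness, which makes the adjusted threshold easier to pass. These shares therefore do not carry over to the measured arrays, where ATP11B at -1.57 did not pass (limma adjusted p = 0.319). The number and the signal of the arrays limit the precision. Gene neighbourhoods were taken from the RefSeq annotation of GRCh38.p14.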

Results

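The series carries the title of a role of ATP11B in platinum resistance, and its arrays ask how silencing ATP11B alters RNA levels in a cisplatin-sensitive ovarian cancer line, A2780-PAR, and in a resistant line, A2780-CP20. Each combination of line and siRNA had 3 arrays. Mean probe intensity was 390 to 467 in 10 of the 12 arrays. It was 61.6 and 70.3 in the arrays labelled A2780-PAR ATP11B siRNA replicates 1 and 2. Probes above an intensity of 100 made up 29.2% to 33.5% of all probes in the 10 arrays, and 2.24% and 4.36% in these 2. Across probes, their median Spearman correlation with the 10 arrays was 0.418 and 0.533, against 0.892 to 0.899 among the 10. The deposited log2 values hide the difference, because every array there has a median of 6.14 and a maximum of 14.11. Results are given for the 12 arrays as designed and then for the 10 arrays, a choice made after the signal had been seen.

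**Figure D1:**
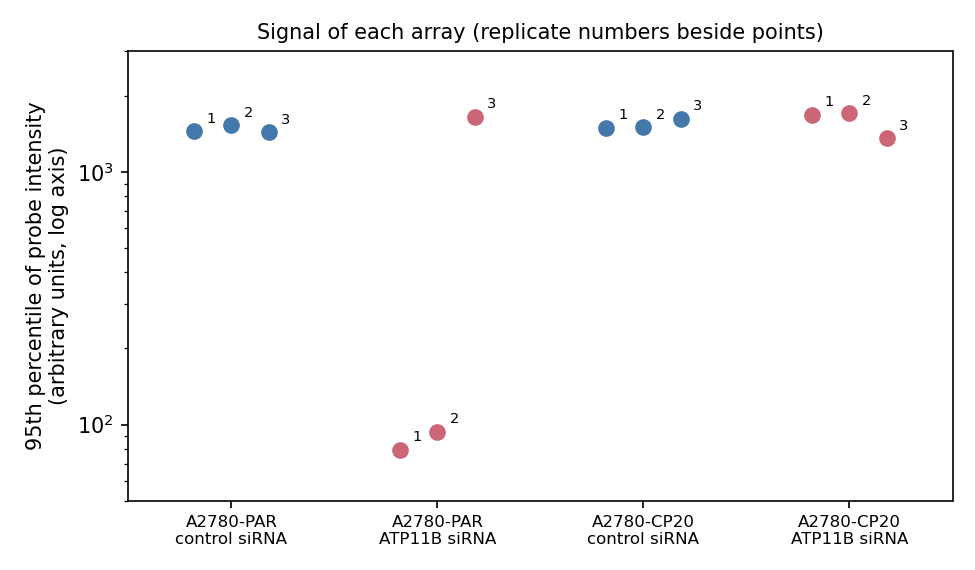
The 95th percentile of probe intensity (arbitrary units, log axis) is plotted for each array, with 1 point per array, grouped by line and siRNA. The arrays labelled A2780-PAR ATP11B siRNA replicates 1 and 2 lie at 79.4 and 93.8, and the other 10 between 1370 and 1710.

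ATP11B encodes a P4-ATPase, a family of phospholipid flippases, and was the gene targeted by the siRNA. Its brighter probe (ILMN_2124155) was lower under ATP11B siRNA in A2780-CP20, with a log2 mean of 9.68 ± 0.43 (SD, n = 3) against 11.08 ± 0.19 (SD, n = 3) under control siRNA in the 12-array normalisation. In A2780-PAR the means were 9.80 ± 1.78 (SD, n = 3) and 11.16 ± 0.26 (SD, n = 3). The 12-array differences were -1.40 (SE 0.69) in A2780-CP20 and -1.36 (SE 0.69) in A2780-PAR, and neither passed over all genes (limma adjusted p = 1 and 0.206). The array labelled A2780-PAR ATP11B siRNA replicate 2 read 11.68, above all 3 controls of its line, and that of replicate 1 read 8.13. In the 10 arrays the differences were -1.57 (SE 0.23) in A2780-CP20, or 33.7% of control, and -1.75 (SE 0.32) in A2780-PAR, or 29.7% of control from 1 array. The dimmer probe (ILMN_1658884) gave -1.63 and -1.41. ATP11B ranked 2 and 1 by p among all genes in these comparisons, but its adjusted p over all genes was 0.319 and 1. Over its 2 probes alone, the 12 arrays gave the brighter probe a limma adjusted p of 0.0718 in A2780-CP20 and 0.0783 in A2780-PAR, and the dimmer probe 0.00955 (at -1.38) and 0.0783 (at -0.79). In the 10 arrays the adjusted p of the brighter probe was 1.57e-05 in A2780-CP20 and 0.000225 in A2780-PAR. By exact permutation within lines over the 10 arrays p was 0.0125, the smallest that the 80 assignments allow, and in A2780-CP20 by itself the exact p was 0.1, again the smallest possible. ATP11B did not differ detectably between the lines under control siRNA, with -0.09 (SE 0.23) for the brighter probe in the 10 arrays (exact p = 0.7) and -0.08 in the 12.

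**Figure D2:**
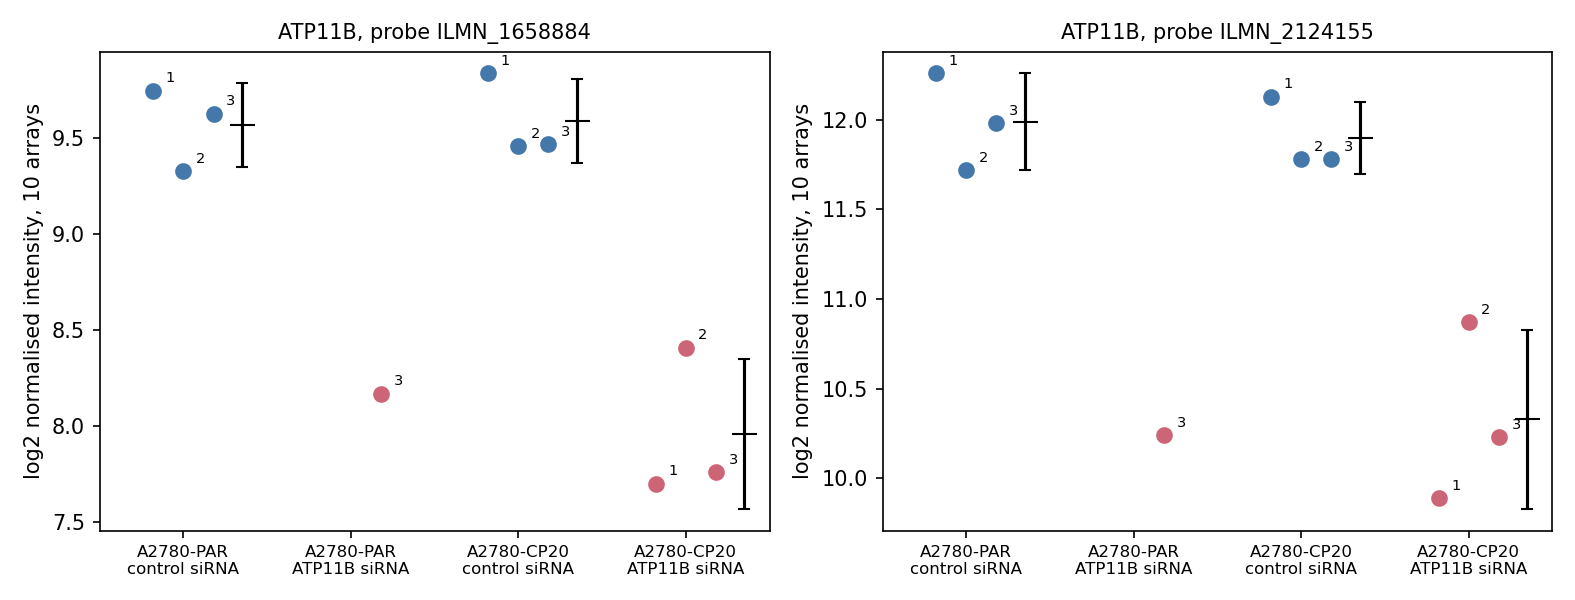
Log2 normalised intensity of both ATP11B probes is plotted for the 10 arrays, 1 point per array with its replicate number, and bars give the mean and SD of groups with 3 arrays. For the brighter probe, ILMN_2124155, ATP11B siRNA arrays of A2780-CP20 lie between 9.89 and 10.87, all below their controls at 11.78 to 12.13.

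The A2780-CP20 comparison asks what ATP11B silencing does in the resistant line. In the 10 arrays the leading genes with higher levels were GANAB at 0.82 (SE 0.12), HABP4 at 0.71 (SE 0.11), TUFT1 at 0.67 (SE 0.13), PRMT6 at 0.58 (SE 0.11) and STAT3 at 0.54 (SE 0.10) on the log2 scale. GANAB encodes a glucosidase subunit of the endoplasmic reticulum, PRMT6 an arginine methyltransferase and STAT3 a transcription factor of cytokine signalling. Besides ATP11B, the leading genes with lower levels were IL1RAP, a subunit of the interleukin 1 receptor, at -0.77 (SE 0.12), the heat shock co-chaperone DNAJB1 at -0.72 (SE 0.12), the trans-Golgi syntaxin STX6 at -0.67 (SE 0.13) and ISOC1 at -0.60 (SE 0.11). Each of these genes had all 3 ATP11B siRNA values on 1 side of the 3 controls, which chance gives for 10% of genes. None passed over all genes, with adjusted p from 0.319 to 0.757. The second STX6 probe gave -0.74 and that of HABP4 0.42. The other probes gave -0.17 and -0.26 for IL1RAP, 0.31 and 0.05 for STAT3, and 0.44 and -0.18 for PRMT6.

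In the 12 arrays the rule named other genes for A2780-CP20. MMP3, a matrix metalloproteinase, was at 0.51 (SE 0.15), PHF5A, a splicing factor subunit, at 0.44 (SE 0.13), PRTG at 0.39, SNORD126 at 0.31 and CRADD at 0.30. ZCCHC12 was at -0.49 (SE 0.12), PLXNA4 at -0.38, CYBA, a subunit of NADPH oxidase, at -0.36, SLC13A3 at -0.35 and OR51G2 at -0.30. PRTG, SNORD126, ZCCHC12, SLC13A3 and OR51G2 did not pass the brightness filter of the 10 arrays. All had an adjusted p of 1. Other probes in the 10 arrays gave 0.39 for PHF5A, but -0.04 and -0.07 for PRTG, 0.10, 0.01 and 0.07 for PLXNA4, and 0.14 and 0.10 for SLC13A3. For A2780-CP20 limma called 0 of 20046 genes in the 12 arrays, with 159 at an unadjusted p under 0.05, and 0 in the 10 arrays, with 872 at that level. The 159 genes are 0.793% of those tested, under the share of 0.05 that chance alone gives. The spread of the 2 arrays of low signal enters this contrast through the common fit. Its median SE was 0.22 in the 12 arrays and 0.119 in the 10, so the 12-array result says little about the response. Groups did not overlap for 10.7% of genes in the 12 arrays, against 10% by chance.

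No gene list was called for A2780-CP20, with a lowest camera adjusted p of 0.0559 in the 12 arrays and 0.572 in the 10. Members of 4 lists passed when adjusted over the list alone in the 10 arrays: DNAJB1 (0.00202) among heat shock genes, CDKN1A at 0.62 (0.00997) among p53 targets, STX6 (0.0126) among trans-Golgi and vesicle genes, and CCN1 at 0.65 (0.0343) among mesenchymal genes. None did in the 12 arrays, where the lowest was 0.529 for CCN2. CDKN1A encodes an inhibitor of the cell cycle. Over whole lists, these genes included, the median was 0.06 over 19 heat shock genes, 0.10 over 24 p53 targets, 0.00 over 45 vesicle genes and 0.02 over 23 mesenchymal genes. Platinum-related lists had small medians, 0.01 for 15 copper and platinum transporters, -0.05 for 9 drug efflux pumps, 0.04 for 9 metallothioneins, 0.01 for 25 glutathione genes, 0.03 for 22 NRF2 targets and 0.04 for 14 other P4-ATPases and their subunits. For DNA repair the medians were 0.01 for 23 nucleotide excision repair genes, 0.04 for 26 homologous recombination genes and -0.01 for 13 mismatch repair and translesion genes. The remaining medians were -0.02 for BCL2 family and IAP genes, -0.02 for lysosomal genes, 0.06 for cholesterol synthesis, -0.04 for the unfolded protein response, -0.03 for interferon-stimulated genes, -0.03 for NF-kB targets, -0.01 for G2/M genes, 0.01 for G1/S genes, -0.06 for hypoxia and glycolysis, 0.02 for epithelial genes, 0.07 for immediate early genes, 0.04 for ribosomal proteins and 0.04 for oxidative phosphorylation. Markers of fibroblasts, leukocytes and endothelium had medians of -0.05, 0.00 and -0.05. The direction of the test was opposite to the median for copper and platinum transporters, G1/S genes and NF-kB targets.

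The A2780-PAR comparison asks the same of the sensitive line. In the 10 arrays, where 1 array stands against 3 controls, the leading genes with higher levels were TPM4, a tropomyosin, at 0.88 (SE 0.18), HABP4 at 0.77 (SE 0.16), the small GTPase MRAS at 0.73 (SE 0.14), ADGRA3 at 0.70 (SE 0.14) and ADSS1 at 0.67 (SE 0.14). Besides ATP11B, RBM24, an RNA-binding protein, was at -0.95 (SE 0.18), DNAJB1 at -0.82 (SE 0.17), CYBA at -0.79 (SE 0.16) and IL1RAP at -0.79 (SE 0.17). TPM4 was at -1.05 in the 12 arrays. ADGRA3 did not pass the brightness filter. The other probes gave 1.07 for TPM4, 0.83 for HABP4, 0.00 and -0.19 for ADSS1, -0.45 for RBM24, and -0.16 and -0.01 for IL1RAP. None of these genes passed, each with an adjusted p of 1. Among other members of the gene lists, STX6 was at -0.82 and HSPA1A, a heat shock protein, at -0.45, again from 1 array. HSPA1A was at 0.18 in the 12 arrays and did not pass the brightness filter. Limma called 0 genes in the 10 arrays, with 645 at an unadjusted p under 0.05, and no gene list, with a lowest camera adjusted p of 0.604. Groups did not overlap for 44.9% of genes, against 50% by chance for 1 array against 3.

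In the 12 arrays the A2780-PAR comparison rests in part on the 2 arrays of low signal. HABP4 was at 1.62 (SE 0.36) from another probe, PCNX3 at 1.60 (SE 0.34), KRTAP4-2 at 0.66, LINC02648 at 0.53 and LYVE1 at 0.47. CNIH2 was at -1.0 (SE 0.18), CYBA at -0.73 (SE 0.11), ARHGEF39 at -0.70, ZCCHC12 at -0.67 and PLA2G3 at -0.62. KRTAP4-2, LINC02648, LYVE1 and ZCCHC12 did not pass the brightness filter of the 10 arrays. All had an adjusted p of 0.122. The remaining probes gave, in the 10 arrays, -0.06, 0.04 and -0.01 for CNIH2, -0.22, -0.04 and -0.09 for ARHGEF39, and 0.03 for LYVE1. Limma called 0 genes, with 6219 at an unadjusted p under 0.05, and groups did not overlap for 15% of genes, against 10% by chance. Camera called 6 lists: hypoxia and glycolysis (median -0.61, adjusted p = 0.00121), trans-Golgi and vesicle genes (-0.61, 0.00248), lysosomal genes (-0.70, 0.00248), G1/S and replication genes (-0.49, 0.0117), leukocyte markers (0.35, 0.039) and p53 targets (-0.57, 0.0498). With an estimated correlation the adjusted p of each was 0.611. Without the 2 arrays of low signal none was called, and the medians became -0.09, 0.04, -0.01, 0.03, 0.05 and 0.03; for trans-Golgi and vesicle genes the mean was -0.01 and the test pointed down. In the 12 arrays members of 9 lists passed over their list alone, with a lowest adjusted p of 0.0305.

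Both responses were compared to ask whether the lines react alike. Limma called 0 genes in both lines in the same direction, in the 12 and in the 10 arrays. Among the 100 genes with the smallest p in each line in the 10 arrays, 15 were shared with the same direction, against 0.25 if the rankings were independent. Of these, 5 were higher, HABP4, TUFT1, TTPAL, PRMT6 and CENPBD1P, and 10 were lower, ATP11B, IL1RAP, DNAJB1, STX6, ISOC1, CYBA, WASF3, ZCCHC12, MROH6 and CPOX, which encodes an enzyme of haem synthesis. ZCCHC12 did not pass the brightness filter. This comparison of leading genes was chosen after the data had been seen. Both rankings use the same estimate of each gene's spread, so they are not independent and the 0.25 is too low a baseline. In the mean response over both lines, 0 genes were called by limma, with 894 at an unadjusted p under 0.05. ATP11B at -1.66 (SE 0.20), IL1RAP at -0.78 (SE 0.10), DNAJB1 at -0.77 (SE 0.10) and HABP4 at 0.74 (SE 0.10) had the lowest adjusted p, 0.0839, followed by STX6 at -0.74 and ISOC1 at -0.65 (0.129), TUFT1 at 0.72 (0.16) and WASF3 at -0.56, GANAB at 0.61 and CYBA at -0.60 (0.205).

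**Figure D3:**
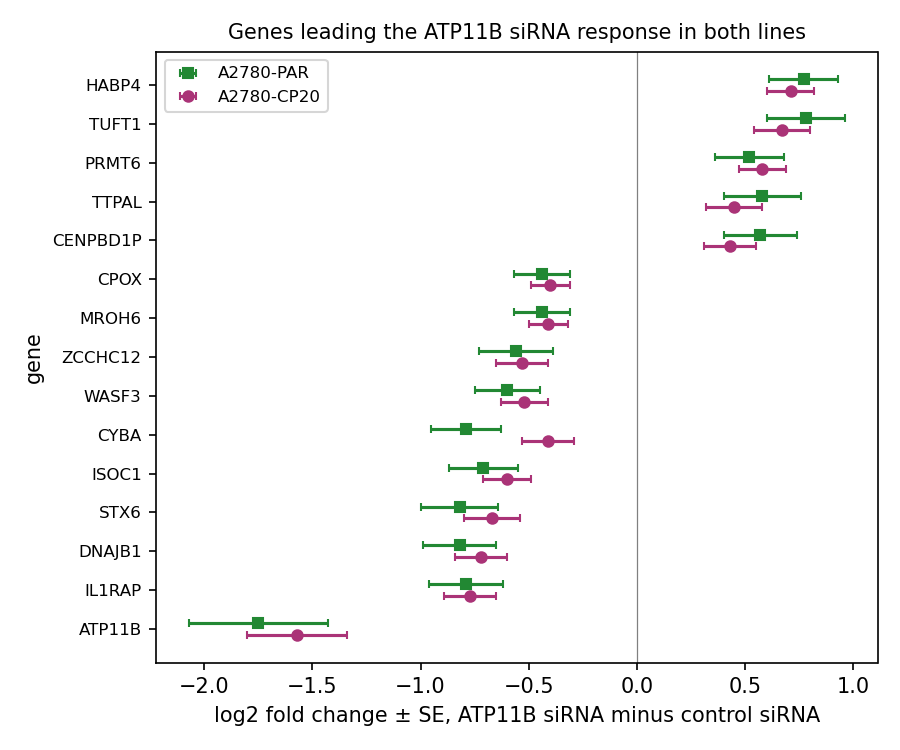
Log2 fold change with its SE under ATP11B siRNA is plotted in the 10 arrays for the 15 genes among the 100 of smallest p in both lines with the same direction; squares are A2780-PAR (1 array against 3) and circles A2780-CP20 (3 against 3). The genes were picked for agreeing in direction, and ATP11B is the lowest at -1.75 and -1.57.

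Between the lines under control siRNA, the comparison asks how the resistant line differs from the sensitive one. In the 10 arrays ALDH1A1, an aldehyde dehydrogenase, was at 1.10 (SE 0.14) in A2780-CP20 relative to A2780-PAR, TM4SF1 at 0.97 (SE 0.13), IGFBP3, a binding protein of insulin-like growth factors, at 0.67 (SE 0.12), MARCKS at 0.65 (SE 0.09) and IRX3 at 0.54 (SE 0.09). S100A4, a calcium-binding protein, was at -1.14 (SE 0.13), the small heat shock protein HSPB1 at -0.95 (SE 0.13), the matricellular protein CCN2 at -0.84 (SE 0.13), and LRRN3 and the proteoglycan DCN at -0.63 (SE 0.09 each). All 3 values of each gene in 1 line lay on 1 side of the other line's, but adjusted p ranged from 0.0754 for S100A4 to 0.276. The second probes gave 0.61 for ALDH1A1, 0.71 for IGFBP3, -1.32 for S100A4, -0.59 for CCN2 and -0.59 for LRRN3, and the other DCN probes -0.54, -0.19 and -0.09. In the 12 arrays the rule named IRX3 at 0.50, TM4SF1 at 0.82, AGR2 at 0.43, ZCCHC2 at 0.49, RNA28SN5 at 0.86, DSCR4 at -0.61, CCN2 at -0.71, LRRN3 at -0.54, HPYR1 at -0.36 and CRADD at -0.34, each with an adjusted p of 1. Second and further probes in the 10 arrays gave -0.13 for AGR2 and 0.91 for RNA28SN5. IRX3, ZCCHC2, DSCR4 and HPYR1 did not pass the brightness filter of the 10 arrays. Limma called 0 genes in the 12 arrays, with 177 at an unadjusted p under 0.05, and 0 in the 10, with 950. The 177 genes are 0.883% of those tested, under the share of 0.05 that chance alone gives. Here too the arrays of low signal enter the common fit, with a median SE of 0.22 in the 12 arrays and 0.119 in the 10. Groups did not overlap for 10.7% of genes in the 12 arrays, against 10% by chance.

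Cytosolic ribosomal protein genes were lower as a list in A2780-CP20, with a median of -0.11 over 44 genes in the 12 arrays (camera adjusted p = 5.63e-05; adjusted p = 0.0623 with an estimated correlation) and -0.10 in the 10 (0.0191; adjusted p = 0.427 with an estimated correlation). Oxidative phosphorylation genes had a median of -0.07 in the 12 arrays (0.00311; adjusted p = 0.755 with an estimated correlation) and were not called in the 10 (0.0796). Adjusted over the list alone in the 10 arrays, S100A4 (8.65e-05) and CCN2 (0.000642) passed among mesenchymal genes, HSPB1 (0.000481) and HSPA1A at -0.31 (0.0403) among heat shock genes, EPCAM at -0.76 (0.00338) among epithelial genes and DUSP6 at 0.92 (0.00505) among immediate early genes. CDKN1A at -0.54 (0.0253) and the copper transporter SLC31A2 at -0.49 (0.0239) passed in theirs. HSPA1A did not pass the brightness filter. The A2780-CP20 control arrays enter this comparison of the lines and the A2780-CP20 response with opposite signs. The lower CDKN1A here and its rise in that response are therefore not independent. The same holds for CRADD, with a mean of 7.62 in the A2780-CP20 controls and 8.03, 8.07 and 7.98 in the other groups. These controls also stood apart for PLXNA4 (6.92 against 6.51, 6.63 and 6.48) and SLC13A3 (6.47 against 6.18, 6.29 and 6.10). They did so too for ZCCHC2 (6.80 against 6.25, 6.49 and 6.45) and CCN2 (7.70 against 8.53, 8.63 and 8.15). Of the fibroblast and stromal markers, DCN (0.000603) and LUM at -0.80 (0.0422) passed, while the list's median was -0.02 over 17 genes. In the 12 arrays only CCN2 passed over its list alone (0.013).

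Averaged over both treatments in the 10 arrays, limma called 5 genes between the lines, a contrast added after the 4 first chosen had given none. TM4SF1 rose by 1.15 (SE 0.11; adjusted p = 0.0164), ALDH1A1 by 1.08 (SE 0.12; 0.0247) and RBM24 by 0.86 (SE 0.11; 0.0407) in A2780-CP20 relative to A2780-PAR. S100A4 fell by 0.99 (SE 0.11; adjusted p = 0.0247) and LRRN3 by 0.63 (SE 0.08; 0.0407). The value of RBM24 rests in part on the single A2780-PAR ATP11B siRNA array, at 7.60 against a mean of 8.55 in the controls of that line: under control siRNA alone RBM24 was at 0.53, and its second probe averaged 0.61. A replicate block, or leaving out A2780-PAR control replicate 1, A2780-CP20 control replicate 1 or A2780-CP20 control replicate 3, left 0 calls. Camera called ribosomal proteins (0.0481) and oxidative phosphorylation (0.0242) as lower in this contrast, each with an adjusted p of 0.537 with an estimated correlation.

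The difference between the responses was tested directly. In the 10 arrays ADPGK at 0.74 (SE 0.18), SERTAD3 at 0.76, PASD1 at 0.78, LCN15 at 0.62 and SPACA7 at 0.58 led the genes with a higher response in A2780-CP20, and GOLGA8A at -0.83 (SE 0.19), MRAS at -0.80 (SE 0.18), ADGRA3 at -0.73, HTATSF1P2 at -0.69 and SMPD4 at -0.69 those with a lower one, each with an adjusted p of 1. In the 12 arrays they were HEXIM2 at 0.91 (SE 0.22), CLDN14 at 0.86, KLF5 at 0.74, MT1G, a metallothionein, at 0.66 and GALM at 0.65, and HNRNPU at -1.70 (SE 0.42), PLET1 at -0.61, LINC01257 at -0.58, SLC13A3 at -0.50 and MIR570 at -0.46, each with an adjusted p of 0.419. From the 10 arrays, other probes gave 0.04 for HNRNPU, 0.14 for PLET1, 0.24 for LINC01257, 0.27 and 0.14 for SLC13A3, -0.18 and -0.18 for CLDN14, 0.03 and 0.35 for SERTAD3, and -0.14 for SMPD4. PASD1, LCN15, SPACA7, ADGRA3, KLF5, MT1G, PLET1, LINC01257, SLC13A3 and MIR570 did not pass the brightness filter of the 10 arrays. The response of ATP11B itself differed by -0.04 (SE 0.98) in the 12 arrays and 0.18 (SE 0.40) in the 10. Limma called 0 genes in the 12 arrays, with 1653 at an unadjusted p under 0.05, and 0 in the 10, with 469. The 6 lists called in A2780-PAR were called here with the opposite sign in the 12 arrays, with camera adjusted p from 0.00523 to 0.0287 and 0.533 with an estimated correlation; none was called in the 10 arrays, where the lowest was 0.854. MT1G passed over the metallothionein list alone in the 12 arrays (adjusted p = 0.0269), and no member of a list did in the 10 (lowest 0.174).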

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

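Leaving out the 2 arrays of low signal, every alternative on the 10 arrays, the contrasts averaged over lines or treatments and the removal of residual axes were chosen after the data had been seen. ATP11B kept its direction under every alternative run in both responses, from -3.60 to -0.10 in A2780-PAR and from -1.77 to -1.19 in A2780-CP20. Leaving out single arrays gave -2.42 to -0.57 and -1.61 to -1.19. Its 12-array results did not pass over all genes, nor did the 10-array results with the same model. In A2780-CP20 it passed on the 10 arrays with a trended robust variance (-1.57), array weights (-1.77), and 1 or 2 residual axes removed (-1.57 and -1.57). In A2780-PAR, with 1 array, it was -1.75 with 2 axes removed. The axes are taken from the residuals, so removing them leaves the fold change as it was and shrinks the residual spread. Passing with axes removed is therefore no evidence of its own. In A2780-CP20 the limma adjusted p ranged from 0.000136 to 1 over the alternatives. Its difference between the lines ran from -0.21 to 0.05 on leaving out single arrays, turning at 0.05 without A2780-PAR control replicate 1; the cause was not tested.

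The 0 genes called in A2780-PAR became 7425 with array weights and 8984 without A2780-PAR ATP11B siRNA replicate 3, with a leave-one-out range of 0 to 8984. For the difference between responses the counts were 6941 and 6718, with a range of 0 to 6718. By construction, that omission leaves only the 2 arrays of low signal in the group; array weights gave replicate 3 the lowest weight of all, 0.0532. For A2780-CP20 the leave-one-out counts were 0 to 0, and the 10 arrays gave 1 gene with a trended robust variance, 3 with array weights, 2 with 1 axis and 41 with 2. For the lines under control siRNA they were 0 to 0, with 1 gene from the 6 arrays compared alone and 7 with array weights; the 10 arrays gave 1 without background correction, 1 with median scaling, 4 with a trended robust variance, 7 with array weights, 13 with 1 axis and 331 with 2. With 2 axes A2780-PAR had 20 genes and both lines shared 5, against 0 to 0 on leaving out single arrays. For the mean response the 10 arrays gave 1 gene with a brightness filter, 1 without background correction, 1 with a trended robust variance, 6 with array weights, 11 with 1 axis and 173 with 2; leaving out single arrays gave 0 to 3, with 3 without A2780-CP20 ATP11B siRNA replicate 2. The cause of these changes was not tested.

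The 5 genes called for the mean difference of the lines became 3 with a brightness filter, 3 with median scaling, 14 with array weights, 21 with 1 axis, 166 with 2 axes and 0 at an adjusted p below 0.01. Leaving out single arrays gave 0 to 6: 0 without A2780-PAR control replicate 1, A2780-CP20 control replicate 1 or A2780-CP20 control replicate 3, 1 without A2780-CP20 control replicate 2 or A2780-CP20 ATP11B siRNA replicate 1, and 2 without A2780-CP20 ATP11B siRNA replicate 2. TM4SF1 and S100A4 were kept by both the filter and the scaling. The 14 list calls over the 4 contrasts became 0 with an estimated correlation, 0 with fry, 33 with median scaling and 4 without A2780-PAR ATP11B siRNA replicate 1 (range 4 to 16); on the 10 arrays they became 1, and 0 with an estimated correlation or fry.

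Replicate numbers paired the arrays only in part, with residual correlations of like-numbered arrays of different groups of -0.08 to 0.36. For replicate 1 of both control groups it was 0.30, against at most -0.09 with unlike-numbered arrays. For replicate 3 of both A2780-CP20 groups it was 0.36, against at most -0.10. In the other comparisons an unlike-numbered array correlated more. Pairing is not excluded, and the results are also given with a replicate block. With it 0 genes were called in each of the 4 contrasts, 12 lists were called, and the mean difference of the lines went to 0 genes.

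Of 97 results on named genes, 2133 values under alternatives comprised 1911 with direction and call as reported, 41 that lost a call, 154 that gained one and 27 that turned. TPM4 in A2780-PAR was -1.05 in the 12 arrays and 0.88 in the 10, with 0.88 (brightness filter), 0.89 (no background correction), 1.04 (median scaling), 0.95 (replicate block), 0.88 (trended robust), 0.81 (array weights), 0.88 (1 axis) and 0.88 (2 axes). HSPA1A in A2780-PAR was 0.18 in the 12 arrays, -0.17 with median scaling, -0.08 with array weights and -0.32 without A2780-PAR ATP11B siRNA replicate 1 (range -0.32 to 0.47); in the 10 it was -0.45, with -0.53 (no background correction), -0.44 (median scaling), -0.43 (replicate block), -0.45 (trended robust), -0.46 (array weights), -0.45 (1 axis) and -0.45 (2 axes). Median scaling turned PCNX3 (-0.60) and HABP4 (-0.06) in A2780-PAR and HNRNPU (0.82) in the difference of responses; with it the median of all genes was -0.107 and 0.12 there. ARHGEF39 was 0.89 in A2780-PAR with the arrays compared alone, PRTG ran from -0.03 to 0.43 in A2780-CP20 on leaving out single arrays, with -0.03 without A2780-CP20 ATP11B siRNA replicate 1, and array weights turned ADSS1 (-0.03) and ADPGK (-0.16). On the 10 arrays p53 targets in A2780-PAR turned (adjusted p = 0.779; 0.882 with an estimated correlation; 0.804 with fry), as did G1/S genes in A2780-PAR (0.967; 0.964; 0.94) and in the difference of responses (0.98; 0.981; 0.965). The cause was not tested.

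A filter on detection p and a slide block were not run; normexp and the absence of a filter are the design itself. Signal over background limits the 2 dim arrays, where nearly all probes lie under an intensity of 100.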

Other observations

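Among the tests below, these were chosen only after the result was seen: the splits behind counts of called genes in all contrasts, every test on the 2 arrays of low signal, the shift of the arrays along the residual axis, and, for the run of neighbouring genes, the shuffles and the check in the ATP11B siRNA arrays. The splits behind list counts, shared genes and the run, and the loading tests, were set beforehand.

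Over both lines in the 10 arrays, 2 drug efflux genes passed when adjusted over their list alone, MVP, the major vault protein, at 0.33 (SE 0.09; adjusted p = 0.0321) and ABCB1, the P-glycoprotein pump, at -0.40 (SE 0.13; 0.0479). Neither passed over all genes. Members of other lists also passed over their list alone, in this contrast and in the mean difference between the lines, with lower adjusted p among them. The A2780-PAR side of the mean response rests on 1 array. Camera did not call the epithelial list for the mean difference between the lines. Averaged over both treatments, EPCAM at -0.74 (0.00121 over its list) and PKP3, a desmosomal plakophilin, at -0.79 (0.0467) were lower in A2780-CP20 among epithelial genes; over all genes the adjusted p was 0.0932 and 0.996.

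The arrays labelled A2780-PAR ATP11B siRNA replicates 1 and 2 were dim at all 3379 bright probes, with 100% of them below all 10 other arrays on both. The other 4 ATP11B siRNA arrays had a mean intensity 1.03 times that of the controls, and no A2780-CP20 array was dim. These 4 were kept because their signal was not low, and only 1 of them is from A2780-PAR. The ratio therefore cannot decide whether ATP11B silencing lowered the signal in A2780-PAR, which stays open. The 100% restates the low signal by which the arrays were picked, and the rank correlation over bright probes, 0.853 at best against at least 0.905 in the other arrays, would also fall from noise near the background, so too little RNA, a failed hybridisation, 1 dimming factor and another sample stay open. In replicate 2 the brighter ATP11B probe read 215, above that array's 95th percentile of 93.8 and above 100% of 731 probes as bright as silenced ATP11B. The dimmer probe, at 83.0, stood at percentile 96.2. Only probes above the array's 95th percentile were judged, so a high rank was likely in advance and the test cannot decide. Silencing as in the other 4 ATP11B siRNA arrays, failed silencing and a wrong label stay open in replicate 2. In replicate 1 the probes read 69.6 and 67.4, under the 95th percentile of 79.4, at percentiles 60.7 and 79.1 of probes as bright as silenced ATP11B. Among probes as bright as ATP11B in the controls they stood at percentiles 4.38 and 72.7 (89.9 and 81.7 in replicate 2; 0.337 or lower in the other 4 arrays), so the brighter probe pointed to less ATP11B and the dimmer did not; this near the background, silencing and its absence cannot be told apart in replicate 1. The rule for these readings was changed after the values were seen, from the brighter probe alone to both probes and then to probes above the array's 95th percentile; replicate 2 was left open under the second.

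The 15 genes shared by both responses may reflect a common response to ATP11B siRNA. As many were shared in 2 of 80 splits of the 10 arrays within lines, the real one included. The median of the other splits was 1 and the highest 25. The comparison was chosen after the data had been seen and counts ATP11B, the target itself. Another split shared more, so chance is not excluded for these 15 genes. On the leading axis of residual variation (46.9% of it) their loadings lay at percentile 1.55 of random genes, and in a test added after that value the positions of the arrays along the axis gave a median of -1.6% of their shift. Genes of small p have small residuals and so small loadings, so neither test decides, and that axis stays open. Effects of the siRNA on genes other than its target were not tested and stay open, as does a direct effect of losing ATP11B.

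Runs of neighbouring genes were searched in 3 contrasts, the lines under control siRNA, the mean difference of the lines and the mean response. A run of 15 genes from ATP2B1 to METAP2 had a mean of -0.27 in A2780-CP20 relative to A2780-PAR over both treatments in the 10 arrays, with all 15 lower; it holds LUM at -0.88, DCN at -0.59, SOCS2 at -0.43 and KERA at -0.34. By two-sided permutation of the gene order, a mean as large in size had p = 0.001, the smallest that 1000 shuffles can give, and the run, chosen in the control arrays, lay at percentile 0.0775 of runs in the ATP11B siRNA arrays. Its loading on the residual axis was at percentile 6.06 of runs, inside the central 95%. However, 25 of 80 splits of the arrays within treatments gave a run as extreme somewhere (0.269 in the real split, 0.443 at most in the others), so chance is not excluded, and arrays of the lines overlapped (-0.03 to 0.26 in A2780-PAR, -0.25 to 0.11 in A2780-CP20). A lower copy number there was not tested.

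Other splits were counted for each set of calls. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and where the real split calls 0 any split gives as many, so those counts decide nothing. For A2780-PAR the real split called 0 genes and the highest other 1 (10 of 10 splits as many), and 6 lists against 5 (1 of 10). For A2780-CP20 the values were 0 genes against 0 (10 of 10) and 0 lists against 2 (10 of 10), and for the lines under control siRNA 0 genes against 0 (10 of 10) and 2 lists against 1 (1 of 10). For the difference of responses the 0 genes are met by 100 of 100 drawn splits, with 0 as the highest other, and for the mean response in the 10 arrays by 80 of 80, with 356 as the highest. At least 6 lists were called for the difference of responses in 15 of 100 drawn splits, with 7 as the highest other, so chance is not excluded for these lists. For the mean difference of the lines 3 of 80 splits gave at least 5 genes, but the highest other gave 759. The contrast and this test were chosen after the data had been seen, so chance is not excluded for these genes. With 2 residual axes removed, 37 of 80 splits gave at least 173 genes (highest other 1940) and 33 of 80 at least 166 (highest other 2600), so no call is taken from those fits. Splits that call many more genes than the real one, with 46.9% of the residual variation on 1 axis, point to a structure of the samples, whose source was not identified.

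Small noncoding RNAs were picked from the leading genes of that residual axis, so a test on the same axis decides nothing about them: 45 of 103 loaded positively, with a median of -0.05 at percentile 1.32 of random sets, and the guess made about their loading was not borne out. G2/M genes had a median loading of -0.10 (percentile 4.48) and G1/S genes of 0.09 (61.7). The sign of the axis is arbitrary. Its positive end holds A2780-CP20 ATP11B siRNA replicate 3 (0.54) and A2780-PAR control replicate 2 (0.52). Its negative end holds A2780-CP20 ATP11B siRNA replicate 2 (-0.52).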
